A study of Mus musculus with 2 samples.

How the data were processed

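Total RNA-seq was performed on both kidneys of each of 2 mouse pups of the strain B6NCrl on postnatal day 0, per the labels from 10 ng of RNA longer than 200 nt with spike-ins added. RNA was extracted with the mirVana method per the labels' protocols, which also list a manual of the SMARTer Ultra Low kit; the role of that kit is not stated there. The pups had the same mother, so their spread leaves out variation between litters. The labels give 1 group and a replicate number per pup, and do not give the pups' sex.

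The authors deposited a gene table and a transcript table per library. Per the file headers, both tables give an expected count (an estimated number of reads, not normalized), TPM and FPKM for each feature, with posterior mean versions of the expected count and TPM; the set of columns is that of RSEM. The deposited TPM of each library is scaled to the same fixed total over all features, and the deposited FPKM is scaled by effective length and library total, per the file headers. The transcript tables also give, per the file headers, the percent of a gene's TPM held by each transcript. The text deposited with each library names the assembly mm10 and the GENCODE annotation M4 and states that transcriptome alignments were quantified, each library on its own. The aligner, the software versions and the strand used in counting are not given in the sources used here. Such estimates divide reads that fit several genes or isoforms by a model, so values of near-identical genes are uncertain.

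Each table held 69691 gene features: 43346 Ensembl genes, 26248 features with numeric identifiers (61 to 259 nt), 96 ERCC spike-ins and 1 phiX sequence. Genes were matched by Ensembl identifier without its version to the GENCODE M21 annotation of GRCm38, the same assembly, which named 42462 genes and left 884 without a name. The unnamed genes held 0.225% and 0.228% of TPM in pups 1 and 2, and stayed in all totals. Coordinates are those of M21. Depth was 41584961 and 48823952 expected counts over all features. A count of 0 allows up to 3 counts, or 0.0721 and 0.0614 CPM. Intervals and floors cover counting error only.

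Chosen before the data were examined were 32 gene lists (392 symbols, 23 of them in more than 1 list), 32 gene pairs, 10 pairs of lists and 25 genes for isoforms, as well as the tests, the rule for named genes and all alternatives but those said to be added. The genes named were the 20 of highest mean TPM; in each list up to 4 members of highest mean TPM and the lowest; all sex-linked and glomerular basement membrane genes; every gene of the pairs and of the isoform set; and the 10 genes with the largest difference between the pups in each direction. A few of the genes so named are not reported here. With 1 group no groups were compared, and 2 pups leave 1 residual degree of freedom, so no p-value is given. After the data were seen, the share of random list pairs of the same sizes, and of random gene pairs matched on level, that exceeded the same limits was also counted, and list contrasts were set against the differences of these random lists.

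Detection was a TPM of at least 1 in both pups. Correlation between pups was across genes of log2(TPM + 1). For the biological coefficient of variation, expected counts were rounded to whole numbers and fitted in edgeR 4.0.16 (R 4.3.3) with TMM factors, the default filter on low counts and an intercept alone. The chi-square of the libraries used rounded counts of genes with at least 10 counts in total. List levels are medians of TPM, set against 10000 random lists of the same size drawn from the 14684 detected genes or, where a member was under 1 TPM, from 21474 protein-coding genes. List contrasts and gene pair ratios were taken as log2(TPM + 1) within each pup, which understates differences of low genes. They were called beyond the spread when the mean exceeded the 95th percentile of absolute between-pup differences of 10000 random pairs, matched on level for genes. Differences between pups were log2 ratios of TMM-scaled CPM + 0.1 for genes with at least 50 expected counts in either pup, called at 2-fold. List medians of these ratios were set against 10000 random lists matched on expression in 20 bins; lists with under 3 tested members were left out. Counting intervals are exact binomial at 95% on rounded counts. They carry no added 0.1, which makes the ratios of low genes smaller, so a ratio need not lie centrally in its interval or within it. To find shared sequence, the 50-base windows of each named gene's M21 transcripts were looked up in the transcripts of all other genes. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

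The steps were tested on simulated data. For pup 2 against pup 1, counts were simulated for 16198 genes at the observed spread, with 200 genes changed. Of genes changed 3-, 4- and 8-fold with enough counts (61, 66 and 67 genes), 100% were called, against 0.0268% of 14917 unchanged genes. All genes were simulated at 1 spread and without reads shared between near-identical genes. These rates therefore need not hold for the genes called in the data. The coefficient of variation came back as 0.137 for 0.0734 put in with the 200 changed genes, and as 0.0728 with none changed. Of 400 random lists drawn from 15150 genes, 5.5% lay outside their central 95%. This follows from how the lists were drawn and checks the procedure only. It does not give the rate for real lists, whose genes can vary together.

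Alternatives were another pseudocount, other detection and count limits, posterior mean TPM, FPKM, CPM without length correction, TPM rescaled without the most abundant genes, scaling by DESeq2 1.42.0 size factors, by the total or by the spike-in total, a fold of 1.5, and each pup left out. Added after the data were seen were the removal of a GC and length trend from the ratios between pups, and random lists matched on expression and length. Not used here were the deposited interval bounds; features with numeric identifiers and spike-ins stayed outside the comparisons apart from spike-in scaling. Ahsp and Snhg1 of the gene lists had no match.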

Results

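Kidney RNA from newborn mice of the strain B6NCrl was profiled by total RNA-seq on postnatal day 0, when new nephrons are still forming in the mouse kidney beside older, working ones. The labels place both libraries in 1 group: each held both kidneys of 1 pup, and the pups came from the same mother, so all values rest on n = 2 littermates. The libraries held 41584961 expected counts for pup 1 and 48823952 for pup 2. With a single group there were no conditions to compare; the labels state no question beyond the profile. The comparisons are therefore between genes and gene lists within the tissue, with the spread between the pups as the error. Values are deposited TPM given as mean ± SD over the pups, and coordinates are mm10 (GRCm38).

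In the newborn kidney 14684 genes stood at 1 TPM or more in both pups. Of these, 13214 (89.99%) were protein-coding, 459 processed pseudogenes, 270 antisense genes, 202 lincRNAs and 38 small nucleolar RNAs. Detection of pseudogenes and antisense genes is uncertain, since near-identical genes share reads and the strand used in counting is not given. Separately, pup 1 had 15091 genes at this level and pup 2 had 15022. The median detected gene stood at 16.2 TPM in pup 1 and 15.4 in pup 2. Protein-coding genes held 86.6% and 84.8% of TPM in pups 1 and 2, and the 15 mitochondrially encoded genes, most of which encode respiratory chain subunits, held 7.42% and 8.41%. The pups' profiles correlated across the 15429 genes at 1 TPM or more in either pup, at Pearson r = 0.990 and Spearman rho = 0.991 on log2(TPM + 1); genes are not independent replicates. The biological coefficient of variation over 17606 genes was 7.34%. Among genes at 10 to 100 TPM the absolute log2 difference between pups had a median of 0.12 and a 95th percentile of 0.34. Among those at 1 to 10 TPM these were 0.16 and 0.62. The labels give a separate animal for each library, and the libraries were counted as separate samples. As a check for copies of 1 library, a chi-square of the counts over 19640 genes was 12.4 times its degrees of freedom; this sets 2 animals against counting error alone.

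**Figure D1:**
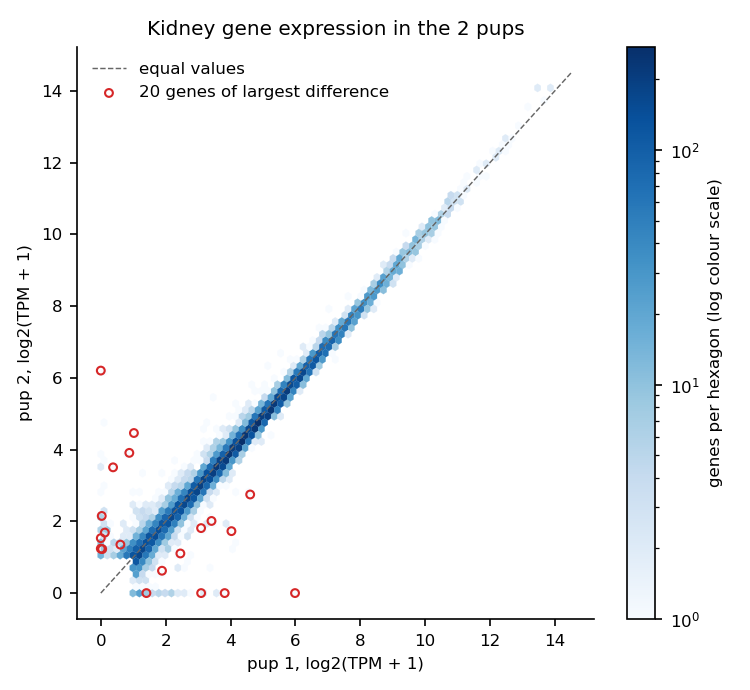
Each axis gives log2(TPM + 1) of 1 pup for the 15429 genes at 1 TPM or more in either pup, with hexagons shaded by the number of genes on a log colour scale. Most genes lay along the dashed line of equal values (Pearson r = 0.990), and red circles mark the 20 genes with the largest difference, 10 in each direction.

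Mitochondrial transcripts, housekeeping genes and a renal calcium-binding protein led the profile. The most abundant gene was mt-Atp6, a subunit of ATP synthase, at 16155 ± 1719.9 TPM, and mt-Atp8, mt-Rnr2, mt-Nd1, mt-Cytb, mt-Co1, mt-Co2 and mt-Co3 also stood among the first 20. S100g, the calcium-binding protein calbindin-D9k of distal tubule cells, reached 4661 ± 406 TPM (ENSMUSG00000040808.4, chromosome X, 162961992 to 162964599). Cytoplasmic actin, Actb, stood at 5831 ± 423 TPM, the ferritin light chain Ftl1 at 5574 ± 327, cyclophilin A, Ppia, at 4669 ± 1.90, and the translation elongation factor Eef1a1 at 3909.5 ± 4.53. Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle on chromosome 12, stood at 13748 ± 3339 and 13748 ± 3340.1 TPM. Gm42418 on chromosome 17, a lincRNA by its annotation, reached 5188 ± 161 TPM. What RNA its reads come from was not tested. The 20 leading genes together held 15.8 ± 1.40% of TPM.

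Several of these levels are uncertain because near-identical sequences share reads. The pseudogene Gm28437 (15491 ± 1049 TPM; ENSMUSG00000101111.1, chromosome 1, 24613189 to 24613971) had 100% of its 50-base windows in mitochondrial genes, and Gm29216 (8036 ± 802 TPM) had 97.1%. The same holds for mt-Atp6, mt-Co2 and mt-Co3 (99.5%, 100% and 99.9% of windows found in another gene), for Rn7s1 and Rn7s2, and for the processed pseudogene Gm10123 (4060.4 ± 19.6 TPM). The 109-nt microRNA gene Gm22133 (4617 ± 233 TPM) lies within Ftl1 on the same strand, so its reads cannot be told from those of Ftl1.

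Nephron progenitor genes were all present at moderate levels. All 12 measured members were detected, with a list median of 18.9 ± 0.930 TPM, at the 60.5th percentile of random lists of detected genes. Cited1, a transcriptional coactivator of uncommitted progenitors, led at 97.4 ± 2.60 TPM (ENSMUSG00000051159.12, chromosome X, 102247381 to 102252181). The thyroid hormone-binding protein Crym stood at 34.5 ± 1.77 TPM, the integrin Itga8 at 31.5 ± 2.33 and Tmem100 at 30.5 ± 1.03. The lowest member was Gdnf, the growth factor that drives ureteric branching, at 4.58 ± 0.219 TPM. Six2, the transcription factor that keeps progenitors undifferentiated, had 9.21 TPM in pup 1 and 15.1 in pup 2.

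Genes of committing and early nephrons were detected for 12 of 12 members, with a median of 21.4 ± 1.07 TPM (percentile 67.1). Cyclin D1, Ccnd1, reached 173 ± 12.01 TPM, the renal transcription factor Pax8 95.8 ± 5.13, the Notch ligand Jag1 37.4 ± 0.877 and the cadherin Cdh6 26.9 ± 3.97, while the Notch target Hes5 was lowest at 4.88 ± 0.325. Renal stroma genes stood higher, with 13 of 13 members detected and a median of 51.6 ± 5.70 TPM (percentile 98.8). The fibrillar collagens Col3a1 (534 ± 37.6 TPM) and Col1a1 (323 ± 57.9 TPM), the opioid precursor Penk (499 ± 18.6 TPM) and the transcription factor Tcf21 (349.6 ± 21.3 TPM) led this list. Foxd1, a transcription factor of stromal progenitors, was its lowest member at 4.54 ± 1.12 TPM.

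Ureteric tip genes were detected for 8 of 8 members, with a median of 30.2 ± 0.590 TPM (percentile 84.8). They were led by Gfra1, the co-receptor through which Gdnf binds Ret, at 44.2 ± 0.396 TPM, followed by the ETS factors Etv5 (37.4 ± 1.32 TPM) and Etv4 (35.4 ± 1.96 TPM) and by Wnt11 (34.96 ± 2.28 TPM). The receptor Ret itself stood at 5.87 ± 0.304 TPM and the lowest member, Sox8, at 1.81 ± 0.233. Genes of the ureteric trunk and collecting duct principal cells were detected for 17 of 17 members, with a median of 46.7 ± 2.65 TPM (percentile 99.2). Aqp2, the vasopressin-regulated water channel, reached 593 ± 64.6 TPM (ENSMUSG00000023013.4, chromosome 15, 99579055 to 99584547), calbindin, Calb1, 365 ± 21.8, and the keratins Krt8 and Krt18 282 ± 23.8 and 212 ± 7.54; Elf5 was lowest at 4.51 ± 0.990. Intercalated cell genes were detected for 10 of 10 members at a median of 13.6 ± 1.12 TPM (percentile 37.5), from carbonic anhydrase Car2 at 175 ± 14.03 TPM, the proton pump subunits Atp6v1g3 (27.97 ± 3.37 TPM) and Atp6v0d2 (17.6 ± 2.51 TPM) and the transcription factor Foxi1 (23.6 ± 0.750 TPM) down to Aqp6 at 1.19 ± 0.240.

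Podocyte genes were detected for 14 of 14 members, with a median of 27.5 ± 1.12 TPM (percentile 88.9). After Tcf21, which the stromal list also holds, the highest were the cell cycle inhibitor Cdkn1c at 325 ± 35.4 TPM, the transcription factor Wt1 at 76.7 ± 0.523 (ENSMUSG00000016458.9, chromosome 2, 105126529 to 105173616) and the surface protein podocalyxin, Podxl, at 68.5 ± 0.276. Nephrin, Nphs1, a slit diaphragm protein, stood at 3.40 ± 0.0919 TPM; Magi2 was lowest at 2.37 ± 0.276. Genes of the parietal epithelium were detected for 5 of 5 members at a median of 52.5 ± 4.61 TPM (percentile 93.4), from Pax8 and the adhesion molecule Ncam1 (61.2 ± 7.40 TPM) to the claudin Cldn1 (29.98 ± 0.467 TPM). The 15 members of the glomerular basement membrane list were all detected, with a median of 45.3 ± 8.97 TPM (percentile 98.5). Whole kidneys were measured, so these levels are not those of glomeruli alone. The collagen IV chains ranged from Col4a1 (229.8 ± 13.9 TPM) and Col4a2 (113 ± 2.09 TPM) over Col4a5 (20.7 ± 0.884 TPM), Col4a3 (17.96 ± 0.608 TPM) and Col4a4 (16.4 ± 0.700 TPM) to Col4a6 (1.72 ± 0.120 TPM). Among laminin chains, Lamb1 stood at 110.2 ± 9.39 TPM, Lamc1 at 86.5 ± 2.72, Lama5 at 45.3 ± 8.97, Lamb2 at 30.2 ± 2.43 and Lama1 at 11.7 ± 1.19. Agrin, Agrn, had 63.4 ± 3.37 TPM, the nidogens Nid1 and Nid2 had 60.3 ± 1.41 and 49.9 ± 4.48, and perlecan, Hspg2, had 26.6 ± 2.14.

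Proximal tubule genes were detected for 21 of 21 members and had a median of 30.3 ± 0.700 TPM (percentile 94.4). Kap, the kidney androgen-regulated protein, led at 741 ± 162 TPM (ENSMUSG00000032758.2, chromosome 6, 133849851 to 133853762). Fbp1, a key enzyme of gluconeogenesis, stood at 449.9 ± 92.1 TPM, the glutathione-degrading enzyme Ggt1 at 287 ± 46.9 and the phosphate transporter Slc34a1 at 245 ± 59.2 (ENSMUSG00000021490.10, chromosome 13, 55398187 to 55415592). The organic anion transporter Slc22a7 was lowest at 1.39 ± 0.170 TPM. In the loop of Henle list, 11 of 12 members were detected, with a median of 15.4 ± 0.194 TPM (percentile 89.2 of random lists of protein-coding genes). The salt cotransporter Slc12a1 reached 179 ± 3.08 TPM, the claudins Cldn10 and Cldn19 165 ± 3.05 and 57.6 ± 0.00707, and uromodulin, Umod, 107 ± 3.18; Cldn14 lay below the detection level at 0.680 ± 0.0990. Of the distal convoluted and connecting tubule genes, 9 of 11 were detected, with a median of 38.8 ± 0.113 TPM (percentile 99.4). After S100g and Calb1 came the kinase gene Wnk1 (135 ± 2.03 TPM) and tissue kallikrein, Klk1 (92.03 ± 25.4 TPM). An estimated 72% of the Wnk1 TPM was Wnk1-201, a transcript without a coding sequence in the annotation, so this is not the level of kinase mRNA. The thiazide-sensitive cotransporter Slc12a3 stood at 31 ± 0.0636 TPM and parvalbumin, Pvalb, at 0.270 ± 0.0990.

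Vascular genes were present throughout. Endothelial genes were detected for 12 of 12 members at a median of 41.4 ± 2.26 TPM (percentile 96.8), led by Egfl7 (167 ± 2.88 TPM), the fenestral diaphragm protein Plvap (156 ± 11.1 TPM), Emcn (96.8 ± 2.92 TPM) and Eng (60.1 ± 4.07 TPM), with the VEGF receptor Flt1 lowest at 8.30 ± 0.177. Genes of mesangium, pericytes and smooth muscle were detected for 12 of 12 members at a median of 34.1 ± 2.17 TPM (percentile 92.7). Smooth muscle actin, Acta2, stood at 448 ± 59.9 TPM and renin, Ren1, at 384 ± 3.37 (ENSMUSG00000070645.5, chromosome 1, 133350510 to 133360325), followed by Gata3 (78.7 ± 3.97 TPM) and Tagln (77.3 ± 11.7 TPM), with Notch3 lowest at 5.74 ± 0.297.

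Blood cell genes were also found. In the leukocyte list 13 of 14 members were detected, at a median of 10.6 ± 1.58 TPM (percentile 78.5 of random lists of protein-coding genes, the background for every list with a member under 1 TPM). The neutrophil protein S100a8 stood at 71.2 ± 2.02 TPM, lysozyme, Lyz2, at 60.98 ± 0.163, the complement subunit C1qb at 49.98 ± 7.25 and S100a9 at 34.5 ± 0.629, against 0.0550 ± 0.00707 for the T cell receptor component Cd3e. In the erythroid list 6 of 10 members were detected, at a median of 8.23 ± 0.371 TPM (percentile 65.4). Adult globins led it, with Hba-a2 at 2018 ± 89.9 TPM, Hbb-bs at 1185 ± 27.6, Hba-a1 at 821 ± 14.98 and Hbb-bt at 502 ± 13.6; the paralogs are near-identical, so the split within each pair is uncertain. The embryonic globin Hbb-y had 0.355 ± 0.0919 TPM and the erythroid transcription factor Gata1 0.0650 ± 0.00707.

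Genes of neighbouring organs and other tissues were mostly below the detection level. The adrenal list had 2 of 11 members detected and a median of 0.340 ± 0.127 TPM (percentile 11.3), with Pnmt, which makes adrenaline, at 2.94 ± 0.184 TPM, the corticotropin receptor Mc2r at 1.80 ± 0.276, and no expected count for Cyp11b2. The gonad list had 1 of 8 detected, Insl3 at 1.08 ± 0 TPM, with a median of 0.0125 ± 0.00354 TPM (percentile 1.28) and no expected count for Hsd17b3. Of the liver, pancreas and gut genes 6 of 12 were detected, at a median of 2.26 ± 1.02 TPM (percentile 27.9). Among these were alpha-fetoprotein, Afp, at 100.2 ± 6.95 TPM, transthyretin, Ttr, at 72.7 ± 4.91, Serpina1a at 22 ± 1.66 and Vil1 at 14.2 ± 0.863, the last of which is also a brush border protein, while the pancreatic protease Prss1 had no expected count. Nerve and glia genes were detected for 2 of 8 members (median 0.453 ± 0.244 TPM, percentile 10.6), among them Stmn2 at 5.22 ± 0.0849 TPM. Skeletal muscle and fat genes were detected for 3 of 9 (median 0.430 ± 0.396 TPM, percentile 14.7), with the fatty acid-binding protein Fabp4, which endothelial cells also make, at 548 ± 33.6 TPM, Tnnt3 at 2.79 ± 0.0636, Acta1 at 1.70 ± 0.389 and Myh3 lowest at 0.03 ± 0.0283. A count of 0 allows up to 3 counts, or 0.0721 CPM in pup 1 and 0.0614 CPM in pup 2.

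Cell cycle and imprinted growth genes had medians above that of detected genes (15.8 TPM), and signalling ligands below it. All lists here but the cell cycle list were set against protein-coding genes, detected or not, so their percentiles are not comparable with its own. Cell cycle genes were detected for 15 of 15 members at a median of 64.9 ± 7.71 TPM (percentile 99.8 of random lists of detected genes), with the mitotic kinase Cdk1 at 191 ± 12.6 TPM, the replication clamp Pcna at 143 ± 15.2, Birc5 at 122 ± 8.54, Ccnb2 at 104 ± 3.99 and Mki67 lowest at 12.6 ± 0.410. Imprinted growth genes were detected for 15 of 16 members at a median of 34.8 ± 0.608 TPM (percentile 99.7), led by Mest (893 ± 10.1 TPM), Cdkn1c, the fetal growth factor Igf2 (254 ± 17.2 TPM) and the lincRNA H19 (159 ± 5.76 TPM), with Kcnq1ot1 lowest at 1.01 ± 0.233. Of the posterior Hox genes 17 of 20 were detected at a median of 20.1 ± 0.735 TPM (percentile 97.9): Hoxa10 stood at 145 ± 0.983 TPM, Hoxd8 at 60.6 ± 0.552, Hoxd9 at 50.6 ± 4.16 and Hoxa9 at 47.4 ± 1.34, while Hoxb13 had no expected count. Signalling ligands of kidney development were detected for 20 of 22 members (median 13.1 ± 0.559 TPM, percentile 91.98), with Pdgfa at 61.5 ± 0.0283 TPM, Wnt11, Bmp7 at 28.1 ± 0.580 and Fgf7 lowest at 0.280 ± 0.0424. Hormone genes of the renin-angiotensin and calcium-phosphate systems were detected for 13 of 14 (median 25.6 ± 1.20 TPM, percentile 98.2). After Ren1 came the parathyroid hormone receptor Pth1r at 139 ± 10.4 TPM, and klotho, Kl, stood at 58.4 ± 9.26; erythropoietin, Epo, had 0.110 ± 0.0849.

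Immediate early and stress genes were detected for 12 of 14 members at a median of 18.2 ± 1.36 TPM (percentile 94.6), from Ier2 (65.3 ± 2.22 TPM) and Jun (46.8 ± 3.95 TPM), Lcn2 (38.03 ± 3.06 TPM) and Dnajb1 (35.4 ± 4.57 TPM) to Fosb (0.06 ± 0 TPM). Hypoxia and glycolysis genes were detected for 11 of 12 (median 22.3 ± 0.675 TPM, percentile 95.9), with lactate dehydrogenase Ldha at 743 ± 47.2 TPM, Pgk1 at 213 ± 15.8, Bnip3 at 103 ± 4.41 and Car9 lowest at 0.700 ± 0.424. The 15 mitochondrially encoded genes were all detected, with a median of 4869 ± 143 TPM (100th percentile of random lists of detected genes) and mt-Nd4l lowest at 136 ± 22.7. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were detected for 11 of 13 (median 5.45 ± 0.297 TPM, percentile 50.4), with Hist1h4d at 207 ± 13.7 TPM, Hist1h1c at 29.8 ± 3.34 and Hist1h4a lowest at 0.0650 ± 0.0919; many histone genes are near-identical, so these levels are uncertain. In the list of long non-coding RNAs 11 of 16 were detected (median 34.8 ± 3.18 TPM, percentile 99.8): after Rn7s1 came Malat1 at 3526 ± 310.2 TPM, Gas5 at 568 ± 68.6 and Rn7sk at 368 ± 62.2, and Hottip had no expected count. Of the sex-linked genes 4 of 10 were detected (median 0.03 ± 0.0212 TPM, percentile 1.23). The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d stood at 60.98 ± 0.912, 28.8 ± 2.37, 13.1 ± 1.39 and 10.1 ± 0.247 TPM in the pups, whose sex label reads not collected. The X inactivation RNA Xist had 0.0350 ± 0.0354 TPM and its antisense partner Tsix 0.02 ± 0.0141. Zfy1 had 0.0150 ± 0.0212, Zfy2 0.01 ± 0.0141, and Sry and Usp9y had no expected count. The strand used in counting is not given in the sources used here, so antisense genes such as Tsix and Kcnq1ot1 cannot be told apart from overlapping transcripts.

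**Figure D2:**
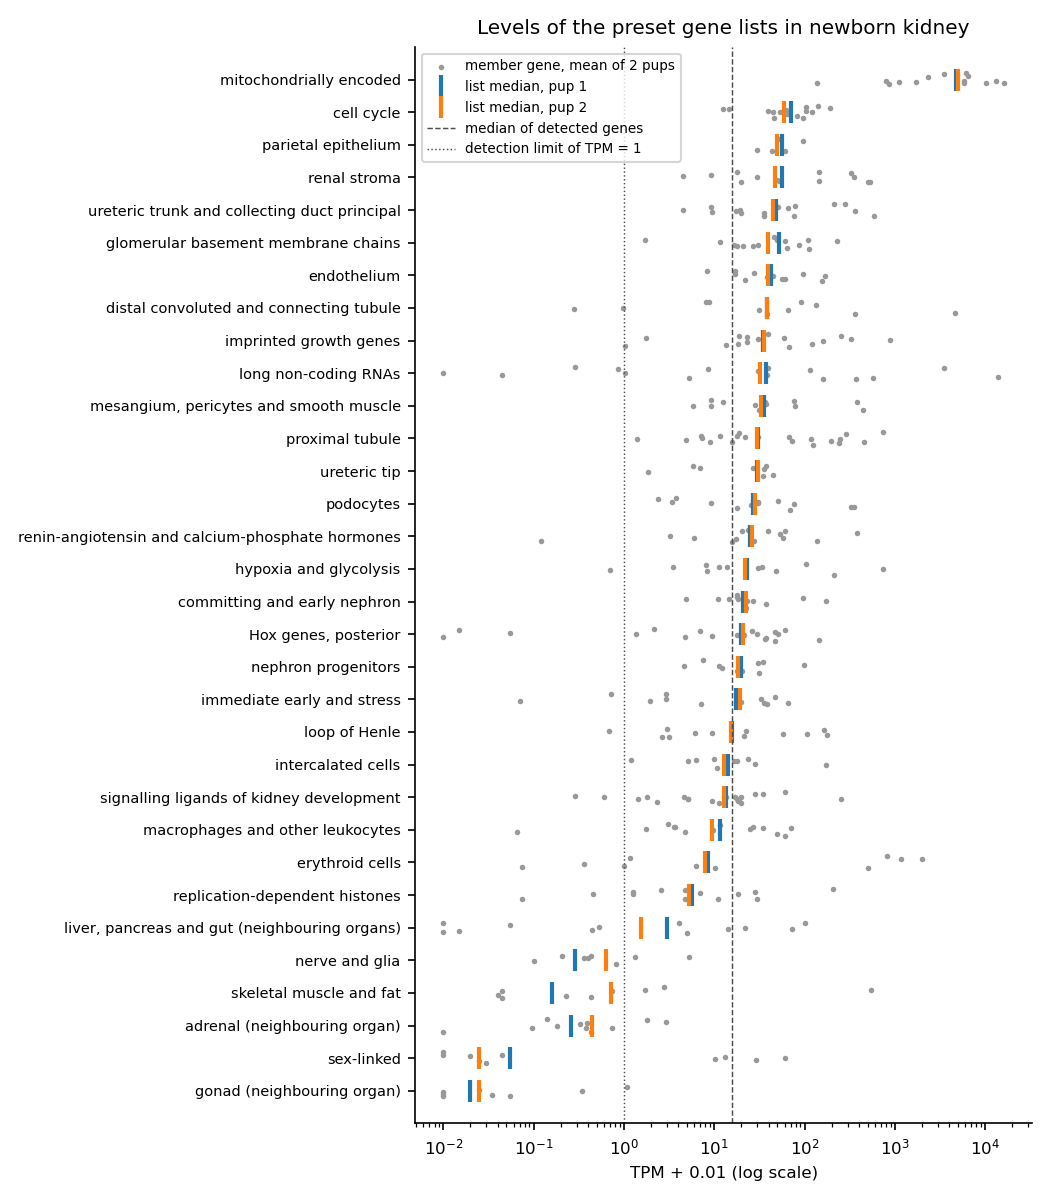
The horizontal axis gives TPM + 0.01 on a log scale, grey points are member genes (mean of 2 pups), and blue and orange marks are the list medians of pups 1 and 2, for 32 gene lists. The medians of 20 lists lay above the median detected gene (dashed line, 15.8 TPM), and those of nerve and glia, muscle and fat, adrenal, sex-linked and gonad genes lay below the detection level of 1 TPM (dotted line).

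Cell-type lists were set against each other within each pup. Stromal genes had a median 2.63-fold above that of nephron progenitor genes on the log2(TPM + 1) scale (log2 1.40 ± 0.09, n = 2). Proximal tubule genes stood above loop of Henle genes (log2 1.03 ± 0.05, 2.04-fold), and loop of Henle genes below those of the distal convoluted and connecting tubule (log2 -1.38 ± 0.01). Nephron progenitor genes stood below proximal tubule genes (log2 -0.65 ± 0.04) and below podocyte genes (log2 -0.51 ± 0.12). Collecting duct principal cell genes stood 3.34-fold above intercalated cell genes (log2 1.74 ± 0.03), and ureteric tip genes below those of the trunk (log2 -0.62 ± 0.11). Endothelial genes exceeded leukocyte genes 3.69-fold (log2 1.88 ± 0.12). Podocyte genes exceeded adrenal genes 21.3-fold, and proximal tubule genes exceeded liver, pancreas and gut genes 11.6-fold. All 10 contrasts were larger than the 95th percentile of between-pup differences of random list pairs, which was 0.33 to 0.40. Random lists of the same sizes, drawn from detected genes or, for a list with a member under 1 TPM, from protein-coding genes, exceeded these limits in 69.4% to 89.6% of pairs. Passing therefore shows a contrast larger than the usual spread between the pups, not an unusual difference. None of the 10 contrasts lay outside the central 95% of the differences of such random lists; podocyte against adrenal genes came closest to its bound (log2 4.41 against 4.44). A list's level depends on the markers chosen for it and is not a share of cells.

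Single gene pairs chosen for kidney development and transport were compared in the same way. Of 32 pairs, 28 exceeded the limit, against 27.3 expected for random gene pairs matched on level. A pass shows only that the mean ratio exceeded the usual difference between the pups. It does not test whether the pups agreed for that pair. The collagen IV chain of early basement membranes, Col4a1, exceeded the later glomerular chain Col4a3 12.2-fold on the TPM + 1 scale (log2 3.60 ± 0.04), Col4a2 exceeded Col4a4 6.55-fold, and Lamb1 exceeded Lamb2 3.57-fold (log2 1.83 ± 0.01). Among laminin alpha chains, Lama1 stood below Lama5 in TPM (log2 -1.86 ± 0.15), but their ratio was -0.02 without length correction, so the difference rests on the estimated lengths. Six2 stood below Cited1 (log2 -2.94 ± 0.50; -3.30 in pup 1 and -2.58 in pup 2), Foxd1 below Six2 (log2 -1.23 ± 0.17) and Pax2 below Pax8 (log2 -2.00 ± 0.12). E-cadherin, Cdh1, exceeded N-cadherin, Cdh2 (log2 2.44 ± 0.04), and Vegfa stood below its receptor Kdr (log2 -1.53 ± 0.12).

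Among transporters, the phosphate carrier Slc34a1 exceeded Slc34a3 107-fold (log2 6.74 ± 0.32), and the glucose carrier Slc5a1 exceeded Slc5a2, the main adult renal form, 3.33-fold (log2 1.74 ± 0.16). Slc12a1 exceeded Slc12a3 (log2 2.49 ± 0.03), Slc22a6 exceeded Slc22a8 (log2 1.85 ± 0.04), Lrp2 exceeded Cubn, its partner in protein uptake (log2 1.33 ± 0.08), and Slc2a1 exceeded Slc2a2 (log2 0.52 ± 0.05). The water channel Aqp1 stood below Aqp2 (log2 -2.33 ± 0.24), and the sodium channel subunit Scnn1a below Scnn1g (log2 -1.49 ± 0.06). Cldn6 exceeded Cldn2 by 0.44 ± 0.02, close to the limit of 0.40 for this pair, and without length correction the ratio turned to -0.61. Among metabolic and growth genes, Igf2 exceeded Igf1 12.8-fold, Pkm exceeded Pklr 106-fold, Fbp1 exceeded Pck1 9.51-fold, and the globin Hbb-bs exceeded Hbb-y 876-fold. H19 stood below Igf2 (log2 -0.67 ± 0.15; -0.21 and no longer past the limit without length correction), Ldhb exceeded Ldha (log2 0.74 ± 0.03), and the vitamin D-activating enzyme Cyp27b1 exceeded the inactivating Cyp24a1 (log2 2.49 ± 0.40). The pairs Angpt1 and Angpt2 (log2 -0.24 ± 0.05), Ret and Gdnf (0.30 ± 0.01), Agtr1a and Agtr2 (-0.23 ± 0.06) and Hoxd11 and Hoxa11 (-0.26 ± 0.07) did not differ by more than the spread of random pairs; without length correction Ret to Gdnf (1.31) and Agtr1a to Agtr2 (-0.83) did.

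**Figure D3:**
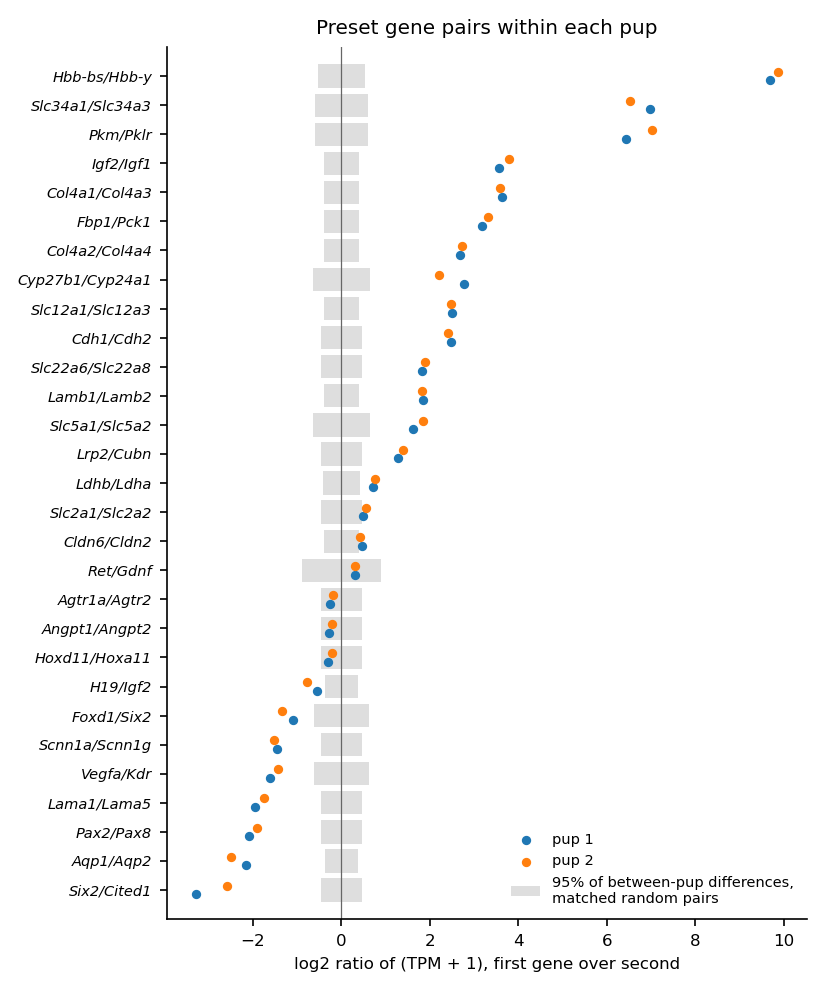
The horizontal axis gives the log2 ratio of TPM + 1 of the first gene over the second for 29 of the gene pairs, with blue and orange points for pups 1 and 2. Grey bars span the 95% of between-pup differences of matched random pairs, and the mean ratio of 25 of these pairs lay beyond its bar, from -2.94 for Six2/Cited1 to 9.77 for Hbb-bs/Hbb-y.

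The leading transcript was the same in both pups for each of the 23 isoform genes with more than 1 listed transcript. Its estimated share exceeded 50% in 18 of these genes and 90% in 7, against 16 and 6 by posterior mean TPM, with Vegfa-201 at 46.8%, Nphs1-201 at 49.4% and Hnf4a-202 at 63.4%. Pkm-201 held 96.1 ± 0.332% of the TPM of pyruvate kinase Pkm, Col4a1-201 99.9 ± 0.0566%, Cdh1-201 99.5 ± 0.375%, Podxl-201 98.4 ± 1.18% and Lrp2-201 93.9 ± 2.81%; Six2-202 held 100%. Umod and Osr1 have 1 listed transcript each. Wnk1-201, a 646-nt transcript without a coding sequence in the annotation (chromosome 6, 119969565 to 119981448), held 72 ± 0.0141% of Wnk1. Intermediate shares were found for Pax8-201 (79.4 ± 1.09%), Ret-202 (78.1 ± 6.11%), Cd44-207 (65.3 ± 0.106%), the retained-intron transcript Fn1-202 (60.8 ± 2.21%), Pax2-203 (54.6 ± 2.72%), Wt1-205 (54.01 ± 1.10%), Tpm1-213 (53.7 ± 1.01%), Igf2-203 (52.6 ± 4.36%) and Vegfa-201 (51.5 ± 4.12%). Slc12a1 was divided between Slc12a1-201 (47.6 ± 1.07%) and Slc12a1-203 (36.6 ± 2.97%). Fgfr1-202 (46.3 ± 3.86%), H19-202 (38.4 ± 0.849%) and Fgfr2-217 (35.4 ± 1.62%) led with under 50%. Among leading transcripts the widest spreads between pups were those of Hnf4a-202 (92.1 ± 10.9%) and Nphs1-201 (54.7 ± 9.99%), against a median SD of 1.18 percentage points. These shares are model estimates from reads that isoforms have in common.

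Differences between the pups compare 2 libraries of littermates, not conditions, and have no replicate check. Of 15150 genes with at least 50 expected counts in either pup, 89 differed at least 2-fold in scaled CPM: 65 were higher in pup 2 and 24 lower. Scaling to the spike-in total lowered the median gene by 0.40 on the log2 scale and gave 30 higher and 89 lower, so directions here are relative to the median gene. Rpl35a-ps3 (ENSMUSG00000067575.5, chromosome 17, 29136972 to 29137304) had 0 expected counts in pup 1 and 620.5 in pup 2, 179-fold higher against a floor of 3 counts in pup 1. Rpl35a-ps2 (ENSMUSG00000081214.3, chromosome 1, 181241988 to 181242320) had 434.1 and 0.01, 167-fold lower against that floor in pup 2. Rpl7a-ps11 (273.4 and 0) and Rpl21-ps15 (85.8 and 0) were 105-fold and 33.1-fold lower in pup 2 against the floor. Rpl9-ps4 was also lower, at a log2 ratio of -1.65. Folds against the floor are not lower bounds, since the floor covers counting error in 1 pup only. It does not cover reads divided between near-identical genes, and the genes set against it here had 98.2% to 100% of 50-base windows in another gene.

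The X-linked gene Xlr3b (ENSMUSG00000073125.6, chromosome X, 73192207 to 73202930) had 56.99 expected counts in pup 1 and 1333 in pup 2, a log2 ratio of 4.24 with a 95% counting interval of 3.95 to 4.75, and its neighbour Xlr4b had 2.48 and 75 counts (3.37, 3.12 to 8.09). E130208F15Rik (0 and 112.6 counts) was 32.4-fold higher in pup 2 and Gm3055 (0.3 and 77.9) 22.5-fold, against the same floor in pup 1. Apod, the lipid-binding apolipoprotein D, had 6 and 56 counts (2.37, 1.80 to 4.52), and Gm2260, Gm26695 and Gm26602 were also higher. In the other direction, Tmem254b (ENSMUSG00000021867.12, chromosome 14, 26203369 to 26207041) had 914.7 and 251.5 counts (-2.05, -2.28 to -1.87) and Tom1, a protein of endosomal sorting, 626.7 and 241.8 (-1.56, -1.80 to -1.37); Gm2274, Gm21451 and Gm15710 were lower too. Each direction also held a gene without a matched name, ENSMUSG00000100934.1 with 0 and 174.6 counts and ENSMUSG00000090407.1 with 56.3 and 0. Of the 18 genes here with a reference sequence, 14 had over 50% of their 50-base windows in another gene, so their counts are uncertain; E130208F15Rik, Gm26695, Gm26602 and Apod had under 10%.

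Proximal tubule genes were lower in pup 2 relative to the median gene, for 18 of 21 members. Their median log2 ratio was -0.23 (0.855-fold), below the central 95% of random lists matched on expression, which ran from -0.07 to 0.07. Slc34a1 had 286.5 TPM in pup 1 and 202.7 in pup 2, Kap 855.5 and 626.1, Fbp1 515.1 and 384.8, and Ggt1 319.9 and 253.5, while Lrp2 had 30.8 and 29.8. Cell cycle genes were lower as well, at -0.12, with 12 of 15 members lower. All 15 mitochondrially encoded genes were higher in pup 2, at a median of 0.28, or 0.15 with the GC and length trend removed, a choice made after seeing the data. Immediate early and stress genes (0.17, 7 of 12 higher), ureteric tip genes (0.13, 7 of 8), long non-coding RNAs (0.13, 7 of 12), leukocyte genes (0.12, 11 of 13), posterior Hox genes (0.12, 12 of 17) and distal convoluted and connecting tubule genes (0.11, 8 of 10) also lay above their random lists. With spike-in scaling, which rests on 307 and 469 counts, the medians of these 7 lists were -0.29 to -0.12, so they were higher relative to the median gene and not under that scaling. Those of proximal tubule and cell cycle genes were then -0.63 and -0.52. These 9 of 30 tested lists compare with 1.5 that random lists of independently drawn genes would give. Genes of 1 list can vary together, and 23 symbols are in more than 1 list. More than 1.5 lists can therefore lie outside between any 2 libraries, and the excess is not a test of the pups. The list of long non-coding RNAs also holds Rn7s1, Rn7sk, Rmrp and Rpph1, which are 271 to 331 nt long (log2 0.24 to 0.87). They also belong to the set of 7 non-coding RNAs weighed below, so these results are not independent. With the GC and length trend removed, the median of the long non-coding RNAs was 0.01 and no longer outside. The other lists lost under some alternative were leukocytes, distal tubule and Hox genes.

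**Figure D4:**
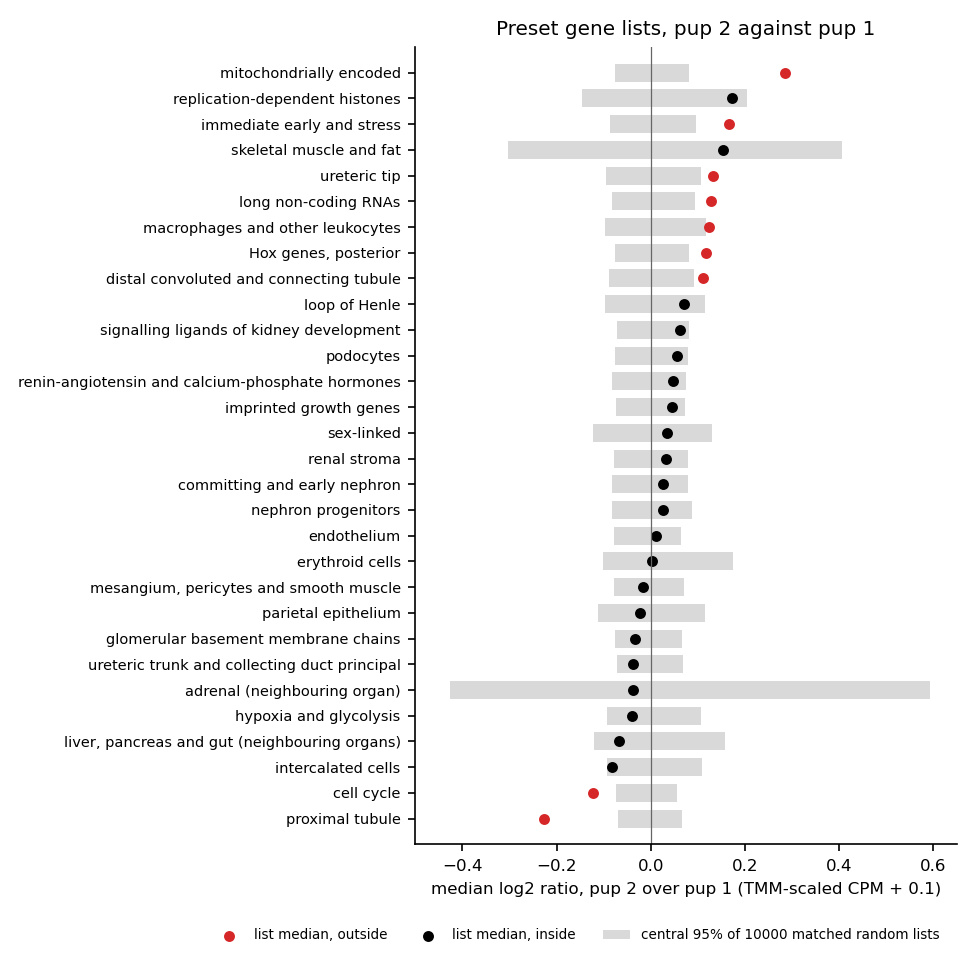
The horizontal axis gives the median log2 ratio of pup 2 over pup 1 in scaled CPM + 0.1 for 30 gene lists, with grey bars for the central 95% of 10000 random lists matched on expression. Red points mark the 9 lists outside their bar, with proximal tubule (-0.23) and cell cycle genes (-0.12) below and 7 lists above, the farthest being the mitochondrially encoded genes (0.28); directions are relative to the median gene.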

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

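No test in this part was chosen after the result was seen. Reads on spike-ins and on features with numeric identifiers lie outside the main measurement and stood above the 3 counts that a count of 0 allows. Spike-in features held 307 expected counts in pup 1, on 19 of the 96 features, and 469 in pup 2, on 25. Their share of all counts was 1.30 times as large in pup 2 as in pup 1, with an exact 95% interval of 1.12 to 1.51 for counting error. Features with numeric identifiers held 12 expected counts in pup 1 and 11 in pup 2, on 5 features in each.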

How the results depend on the processing

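Removal of the GC and length trend and matching on length were chosen only after the results were seen. No paired analysis was possible because the labels give 1 group, so no groups share replicate numbers. All 10 list contrasts kept their direction and stayed beyond the spread under every alternative run, and the leading transcripts of 23 genes stayed the same with posterior mean TPM, although the share of Hnf4a-202 was then 63.4%. Genes detected in both pups ranged from 11030 at a TPM of at least 5 to 17649 at 10 expected counts, with 15022 and 15091 for single pups. The coefficient of variation was 7.31% to 7.69%. Pearson r across genes was 0.973 with a pseudocount of 0.1, and Spearman rho 0.960 without a filter. The 20 leading genes by CPM, of which 13 were the same, held 9.00% of counts; CPM lacks the length correction that raises short genes. Without length correction the Cldn6 to Cldn2 ratio reversed to -0.61, and Agtr1a to Agtr2 (-0.83) and Ret to Gdnf (1.31) moved beyond the spread, which follows from their unequal lengths.

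Counts of genes that differed between the pups moved with the limits that set them. A minimum of 10 expected counts gave 246 higher and 137 lower in pup 2 (383 in all), and a minimum of 200 gave 19 and 8 (27). A fold of 1.5 gave 278 and 107 (385), and TPM + 1 gave 29 and 15 (44). Spike-in scaling gave 30 higher and 89 lower by moving all ratios down; the spike-in total rests on 307 and 469 counts. Of 30 lists (28 with a minimum of 200 counts), 7 to 10 lay outside random lists under the 4 alternatives. Proximal tubule, cell cycle, ureteric tip, immediate early and mitochondrially encoded genes (0.15 with the trend removed) did so under all 4. Long non-coding RNAs did not with a minimum of 200 counts (0.02), with the trend removed (0.01) or matched on length. Leukocyte genes did not with TPM + 1 (0.10) or matched on length, distal tubule genes with TPM + 1 (0.08), and Hox genes with 200 counts (0.07). Podocyte genes moved outside with the trend removed (0.08) and matched on length, hormone genes with the trend removed (0.09), and ligands (0.08) and histones (0.22) with 200 counts. For these lists the cause was not tested. With posterior mean TPM, 137 of 182 gene levels and 26 of 32 list levels stayed within 1 SD; other units rescale all levels. Depth limits calls for low genes: a count of 0 allows 0.0721 CPM in pup 1 and 0.0614 CPM in pup 2.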

Other observations

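Chosen only after results were seen were the gene families, the second proximal tubule list, the removal of the GC and length trend, the set of 7 non-coding RNAs, and the tests on cell share, on gene length and on matched GC content. Among whole gene families, 16 of 23 claudins, which seal and select at tight junctions, were detected in both pups, led by Cldn7 (202 ± 9.14 TPM), Cldn8 (174 ± 1.17) and Cldn10 (165 ± 3.05). All 7 FXYD genes, which encode regulators of the sodium pump, were detected, and Fxyd2 stood at 2187 ± 13.7 TPM against 113 ± 5.81 for Fxyd6. Of 22 genes for subunits of the vacuolar proton pump 21 were detected, with Atp6v0c at 806 ± 39.3 TPM and Atp6v0e at 399 ± 10.9. Of 25 Slc22 transporter genes, which carry organic ions, 21 were detected, led by Slc22a19 (68.4 ± 5.80 TPM), Slc22a6 (67.2 ± 12.5) and Slc22a2 (50.8 ± 7.16). Aquaporins were detected for 8 of 11 genes, with Aqp2 at 593 ± 64.6 TPM, Aqp1 at 117 ± 6.87 and Aqp3 at 76.8 ± 9.98. Inward rectifier potassium channels were detected for 7 of 15, with Kcnj8 at 30.2 ± 2.36 TPM and Kcnj1, the renal outer medullary channel, at 29.8 ± 2.33. Of 19 Wnt ligands 7 were detected, led by Wnt11 (34.96 ± 2.28 TPM), Wnt7b (20.02 ± 0.262) and Wnt5a (19.9 ± 1.89). Wnt4, which drives nephron progenitors to form epithelium, had 14.45 TPM in pup 1 and 21.15 in pup 2.

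Lower proximal tubule expression in pup 2 was weighed first. Apart from the share of cells, no biological explanation was tested, since the design has 1 group. A second list of proximal tubule genes, whose values had not been looked at when it was drawn up, had a median log2 ratio of -0.11 (40 of 51 genes lower; random lists down to -0.05), which argues against a difference limited to the first list. With the GC and length trend removed the first list stood at -0.20, still below random lists (-0.07), which argues against that trend as the whole cause. A smaller share of proximal tubule cells in the RNA of pup 2 may account for the pattern and stays open: it would raise the other cell types alike, and the medians of 7 other lists spanned 0.170 (95th percentile for random lists 0.190). Over all 14 other cell-type lists, from intercalated cells (-0.08) to ureteric tip (0.13), they spanned 0.215 (random 0.251), but with the trend removed 0.222 (random 0.221), which keeps the question open. Cell cycle genes (-0.12, 12 of 15 lower) and mitochondrially encoded genes (0.28, 15 of 15 higher) were not among these lists. Whether a smaller share of proximal tubule cells would account for them too was not tested.

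Higher levels of 7 non-coding RNAs in pup 2 (Rmrp, Rn7s1, Rn7s2, Rn7sk, mt-Rnr2, mt-Rnr1 and Rpph1; log2 0.24 to 0.87, median 0.44) were weighed next, again with no biological explanation tested. Protein-coding genes in the GC range of the set had a median of -0.0015 over 13792 genes, but that range holds nearly all of 13856 tested genes, so its low median excludes nothing. Sets matched to each RNA on GC content had a median of 0.12, with a central 95% from -0.04 to 0.32 that includes 0.50 times the set median (0.218), and the RNAs were chosen after their values were seen, with the near-identical Rn7s1 and Rn7s2 both counted, so GC content stays open. Gene length bias cannot be told apart for the set as a whole. Protein-coding genes of 600 nt or less had a median of 0.184 over 256 genes. That lies below 0.218, but above the 0.178 that would exclude it. The set also holds mt-Rnr1 (955 nt, log2 0.28) and mt-Rnr2 (1582 nt, 0.40). Protein-coding genes of 600 to 1000 nt had a median of 0.086, and those of 1000 to 2000 nt 0.007. The 15 mitochondrially encoded genes, which include both RNAs, stood at 0.15 with the GC and length trend removed (random lists up to 0.05). These values argue against that trend as the whole cause for mitochondrially encoded genes. The other 5 RNAs are 271 to 331 nt long. Protein-coding genes of up to 400 nt had a median of 0.244 over 39 genes, above 0.218. Those of 400 to 600 nt had 0.181 over 217 genes. A difference in the length of RNA kept in the libraries may therefore contribute to the higher levels of those 5 RNAs.

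The largest single-gene differences between the pups were weighed last, without a biological explanation tested. The 18 named genes with a reference sequence had a median of 92.3% of 50-base windows in another gene, against an upper bound of 0.968% for the central 95% of random sets of tested genes. This is consistent with reads being assigned to different near-identical copies in the 2 libraries, as a hypothesis. By windows, it leaves out E130208F15Rik, Gm26695, Gm26602 and Apod, which had under 10% of windows shared. The expected counts of E130208F15Rik (112.58 in pup 2), Gm26695 (1.09 and 56.5) and Gm26602 (4.65 and 95.22) were not whole numbers. Reads shared with other features are therefore not excluded for these genes.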
